A study of Homo sapiens with 3 samples.

How the data were processed

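The series holds 3 one-colour oligonucleotide arrays of HSC-3 cells, an established human tongue squamous carcinoma line. One culture was left untransfected, another received a plasmid for green fluorescent protein (GFP) and the last a plasmid for DKK3 with an HA tag. Per the labels, RNA was taken 24 hours after transfection from cells grown in medium with 10% serum, then amplified, coupled to the dye Cy5 and handled by the array maker's protocol. Each group is 1 array. There were therefore no replicates, no test across samples and no p-value for any gene, and the number of arrays limits the precision of every value. A treatment label also speaks of cultures of another, mouse, cell line, but title, description and source of all 3 samples name the human tongue line.

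The scanner files hold the median intensity of each spot, merged from several scanner gains by least-squares lines, per the file headers. The scanner software is not given in the sources used here. A second brightness column, headed as a background, followed the spot's own intensity with correlations of the log2 values from 0.993 to 0.998 across spots, so it was not subtracted as local background. Each array carried 27456 spots, 24460 of them gene probes and 2680 of them blanks. The series value table, deposited by the authors, also holds intensity on a linear scale. Its values were a straight line of the spot column, with residuals of at most 0.514, that reached 0 near the mean of the blanks and was scaled to a median of 25 on each array. These steps were deduced from the values, and the table lists no value for dim probes.

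From the spot intensities, background was corrected with normexp at an offset of 50 in limma 3.58.1 (R 4.3.3), control spots were removed, and the 3 arrays were quantile normalized and put on the log2 scale. 6 gene probes marked as faulty on an array were left out, which kept 24454. A probe counted as detected where its spot exceeded the mean plus 2 SD of the blanks. Those limits were an intensity of 40.8 on the untransfected array, 33.8 on the GFP array and 36.6 on the DKK3 array. The detected probes numbered 18000, 17213 and 17340 in that order, 16963 probes passed on all 3 arrays, and 18151 passed on at least 1. A positive control printed on 24 spots varied by 5.97%, 5.88% and 6.11% (coefficient of variation) within the arrays.

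Gene names came from the platform annotation, which is of older date. Of the kept probes, 20231 had 1 symbol, 0 had several and 4223 had none. Of the symbols on probes, 17234 were current in the RefSeq gene table of assembly GRCh38.p14, 2898 were updated through a unique synonym and 99 stayed as in the annotation, which gave 17556 genes. Different probes of a gene were kept apart for counts and named genes, and detected probes were averaged for gene lists. No probe carried the name GFP, and no probe sequence or genome position was used.

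A probe was called higher or lower in a comparison when its log2 difference was at least 1 (2-fold) in size and it was detected on at least 1 of the arrays compared. This is a rule of size and describes these arrays. On simulated data with 17104 probes in the DKK3 against GFP comparison, 100% of 50 probes raised 4-fold were called, with a median difference of 1.76, and 0% of 50 raised 2-fold, with a median of 0.80. Of probes lowered to 0.25 of their level 78% were called, of those lowered to 0.5 of it 12%, and of 16904 unchanged probes 0. The settings together thus understated these differences. The changed probes were drawn from spots well above the blanks, so dim probes were not tried, nor were spots bright on a single array. By its form an added offset shrinks log2 differences most for dim probes.

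The design, the main settings, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took DKK3 first. It then took the 15 genes higher and the 15 lower on the DKK3 array, ranked by the smaller of the differences from the GFP and untransfected arrays, both of the same sign. For transfection it took the 10 genes higher and the 10 lower by the smaller of the differences of the GFP and DKK3 arrays from the untransfected array. For each list it took the 3 members with the largest DKK3 minus GFP difference, or up to 4 where the list stood apart. A probe detected on only 1 side of a difference was given as at least N-fold, against the higher of the lowest detected level and its own level.

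For 30 gene lists and 5 marker lists of other cell types, the median log2 difference of the detected members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart outside the central 95%, and lists with fewer than 5 detected members were not placed. Of 30 lists of randomly drawn genes, 1.5 would stand apart. On simulated data 5 of 100 unchanged lists of 25 genes stood apart, and 100 of 100 lists raised by 0.1. The percentile describes these arrays and is no test of the conditions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

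Alternatives were median scaling, 75th percentile scaling, cyclic loess, plain subtraction of the blank level with a floor, no background correction, an offset of 16, the authors' deposited values, detection at 4 SD, detection on all 3 arrays, no filter, and a 1.5-fold threshold. For the lists, random lists without matching, the brightest probe per gene, the mean in place of the median, and lists without the named genes were also tried. Leaving out the spots of blocks 22 to 24 and subtracting the median of each block and row were added after seeing the data. The deposited table was used only as an alternative and for the values credited to it.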

Results

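The 3 arrays addressed which genes differ in HSC-3 tongue carcinoma cells when DKK3, a secreted glycoprotein of the Dickkopf family, is overexpressed. The DKK3 array was set against the GFP array, which carries the effect of transfecting a plasmid, and against the untransfected array. The GFP and untransfected arrays were set against each other for the effect of transfection itself. Each group was 1 array without replicates, so all differences describe these 3 RNA samples. The arrays resembled one another closely, with correlations of log2 intensity across probes of 0.994 for DKK3 and GFP, 0.995 for GFP and untransfected, and 0.993 for DKK3 and untransfected. Probes are not independent replicates. A robust SD of the differences between probes of 0.084, 0.084 and 0.079 log2 units in that order gives the scale of a typical difference between arrays.

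DKK3 was the gene furthest above both other arrays on the array labelled DKK3. Its single probe read 64328 intensity units there, 749 on the GFP array and 539 on the untransfected array. The normalized difference was 6.01 on the log2 scale against GFP, or 64.4-fold, and 6.42 against untransfected cells. In the authors' deposited table DKK3 stood at 31072, 302 and 255 on the DKK3, GFP and untransfected arrays. GFP minus untransfected was 0.41. Quantile normalization gives the brightest probe of each array the mean of the 3 maxima, and without it the DKK3 difference from GFP was larger, 6.50 with median scaling and 6.63 with cyclic loess.

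Against the GFP array, the genes of the unfolded protein response, which fold proteins in the endoplasmic reticulum or remove them from it, were higher on the DKK3 array almost throughout. Of 28 detected members 26 were above 0, with a median difference of 0.18, or 1.13-fold, at percentile 100 of the random lists, whose central range ran from -0.045 to 0.053. None of the members reached 2-fold. The membrane protein HERPUD1 of ER-associated degradation was higher by 0.57, the chaperone partner SDF2L1 by 0.48, the co-chaperone DNAJB9 by 0.46 and the disulfide isomerase PDIA4 by 0.43. The list was also higher on the DKK3 array than on the untransfected array (median 0.21, 27 of 28 above 0), while GFP minus untransfected had a median of 0.031 inside the random range.

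Genes of NF-κB signalling and inflammatory cytokines came second, with 25 of 32 above 0 and a median of 0.14 (percentile 100). The neutrophil chemokines CXCL8, CXCL2 and CXCL1 were higher by 0.72, 0.63 and 0.53, and the cytokine IL1B was lower, at -0.79. The IL1B spot lies in blocks 22 to 24 of the array, where 13 of the 15 genes named as lower on the DKK3 array were printed. YAP-TEAD targets were above 0 for 18 of 20 members with a median of 0.093 (percentile 99.9), among them YAP1 at 0.27, DLC1 at 0.23 and CCN1 at 0.21. ARHGEF17 of the same list was at -1.29, and its probe was bright on the GFP array alone. Angiogenesis factors had a median of 0.093 (percentile 99.8) with 11 of 18 above 0. The Notch ligand JAG1 was higher by 0.64, the ephrins EFNB2 and EFNA1 by 0.36 and 0.31, and SEMA3C, from blocks 22 to 24, was at -0.74. Genes of the ATF4 stress and amino acid response had a median of 0.059 (percentile 98.5, 22 of 30 above 0). The cystine transporter SLC7A11, the transcription factor DDIT3, the pseudokinase TRIB3 and the asparagine synthetase ASNS were higher by 0.39, 0.39, 0.33 and 0.27.

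5 lists were lower on the DKK3 array than on the GFP array. Cholesterol synthesis had a median of -0.14 (percentile 0.01), with 3 of 21 detected members above 0. HMGCS1, which makes the precursor of mevalonate, was at -0.37, the farnesyl diphosphate synthase FDPS at -0.36, ACAT2 at -0.33 and the sterol sensor partner INSIG1 at -0.31. Oxidative phosphorylation had a median of -0.074 (percentile 0.76, 6 of 27 above 0), with COX7B at -0.65 and NDUFS8 at -0.45. Against untransfected cells NDUFS8 was higher on both arrays, by 0.59 with GFP and 0.15 with DKK3. COX7B was at -0.089 with GFP and -0.74 with DKK3. Interferon-stimulated genes had a median of -0.066 (percentile 0.05, 10 of 43 above 0), with IFI6 at -1.45, IFIT1 at -0.39 and OAS1 at -0.39. Replication-dependent histones, at -0.058, lay just outside the random range (percentile 2.36, 2 of 16 above 0; H2BC12 at -0.44). Keratinocyte differentiation genes had a median of -0.047 (percentile 0.37, 6 of 24 above 0). The proteases KLK5 and KLK6 were at -0.38 and -0.29 and the alarmin S100A8 at -0.28, while RPTN, a cornified envelope protein, was detected on the DKK3 array alone, at least 1.31-fold above GFP.

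The other 20 lists stayed inside the random range in this comparison. In the DKK family, receptors and Wnt inhibitors, DKK3 was the 1 member at 2-fold among 16 detected, and the list's median was -0.012, with the receptor gene KREMEN2 at -0.55 and DKK1 at 0.33. Wnt and β-catenin targets had a median of -0.015 (CTNNB1 itself 0.41, PLAUR 0.20), Wnt ligands and Frizzled receptors 0.020 (WNT11 0.24, WNT5B 0.23), and the PI3K-AKT-mTOR pathway 0.0215 (GSK3B 0.34, GSK3A -0.24). The medians were 0.0155 for S phase and mitosis (MAD2L1 0.35, CCNA2 -0.89 in blocks 22 to 24), 0.028 for MYC targets, -0.015 for p53 targets (DDB2 -0.82 in blocks 22 to 24), 0.010 for apoptosis regulators and 0.0085 for the heat shock response. Among lists of tissue identity and invasion, mesenchymal genes had a median of 0.037 (LOX 0.30, SNAI2 0.22, FN1 0.20), matrix proteases 0.035 (SERPINE2 0.34, MMP14 0.24), epithelial junction genes 0.018 (CLDN3 -1.23, bright on the GFP array alone), basal keratinocyte genes -0.011 (KRT15 -0.53), integrins -0.012 (ITGA2 0.33) and TGF-β targets -0.0023 (INHBA 0.40). The EGFR and ERBB list stood at -0.0115 although the receptor gene MET was higher by 0.62. Immediate-early genes stood at 0.027, with the EGFR ligand HBEGF higher by 0.66 and PHLDA1 by 0.39. Hypoxia and glycolysis stood at -0.0037, cytosolic ribosomal proteins at -0.0066 and antiviral interferons and chemokines at -0.034. Of the marker lists for other cell types, leukocyte markers (-0.0033) and skeletal muscle markers (-0.0038) stayed inside the random range, and too few fibroblast and endothelial markers were detected (3 and 4) to be placed. Neural markers stood apart at -0.11 over 7 genes, led by GFAP, which was bright on the GFP array alone and, not detected on the DKK3 array, at least 2.33-fold lower there.

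10 of 30 lists thus stood apart between DKK3 and GFP, against 1.5 for lists of randomly drawn genes. That number does not allow for genes of a list varying together between cultures. The unfolded protein response, NF-κB, cholesterol and interferon-stimulated lists stood apart in 16 of 16 alternatives. The others fell inside the random range in 6 (histones), 5 (ATF4, median scaling at 0.015 among them), 2 (angiogenesis and keratinocyte differentiation each) and 1 (YAP-TEAD and oxidative phosphorylation each) of the 16. The mean in place of the median was 1 of these for the ATF4, angiogenesis (0.056), YAP-TEAD (0.039) and keratinocyte (-0.0581) lists. The angiogenesis list also lay inside with no filter on dim probes, and its lowest value among the 16 was 0.0085. With the spots of blocks 22 to 24 left out, an alternative chosen after seeing the data, the lists of oxidative phosphorylation (-0.033), keratinocyte differentiation (-0.023) and histones (-0.051) no longer stood apart and the lists of mesenchymal genes (0.11) and matrix proteases (0.062) did. The genes named above with a spot in blocks 22 to 24 also include KREMEN2, COX7B, KLK5, IFI6, IFIT1 and CLDN3. GSK3A had a probe there at -0.42, while its other probe, printed elsewhere, stood at -0.056.

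**Figure D1:**
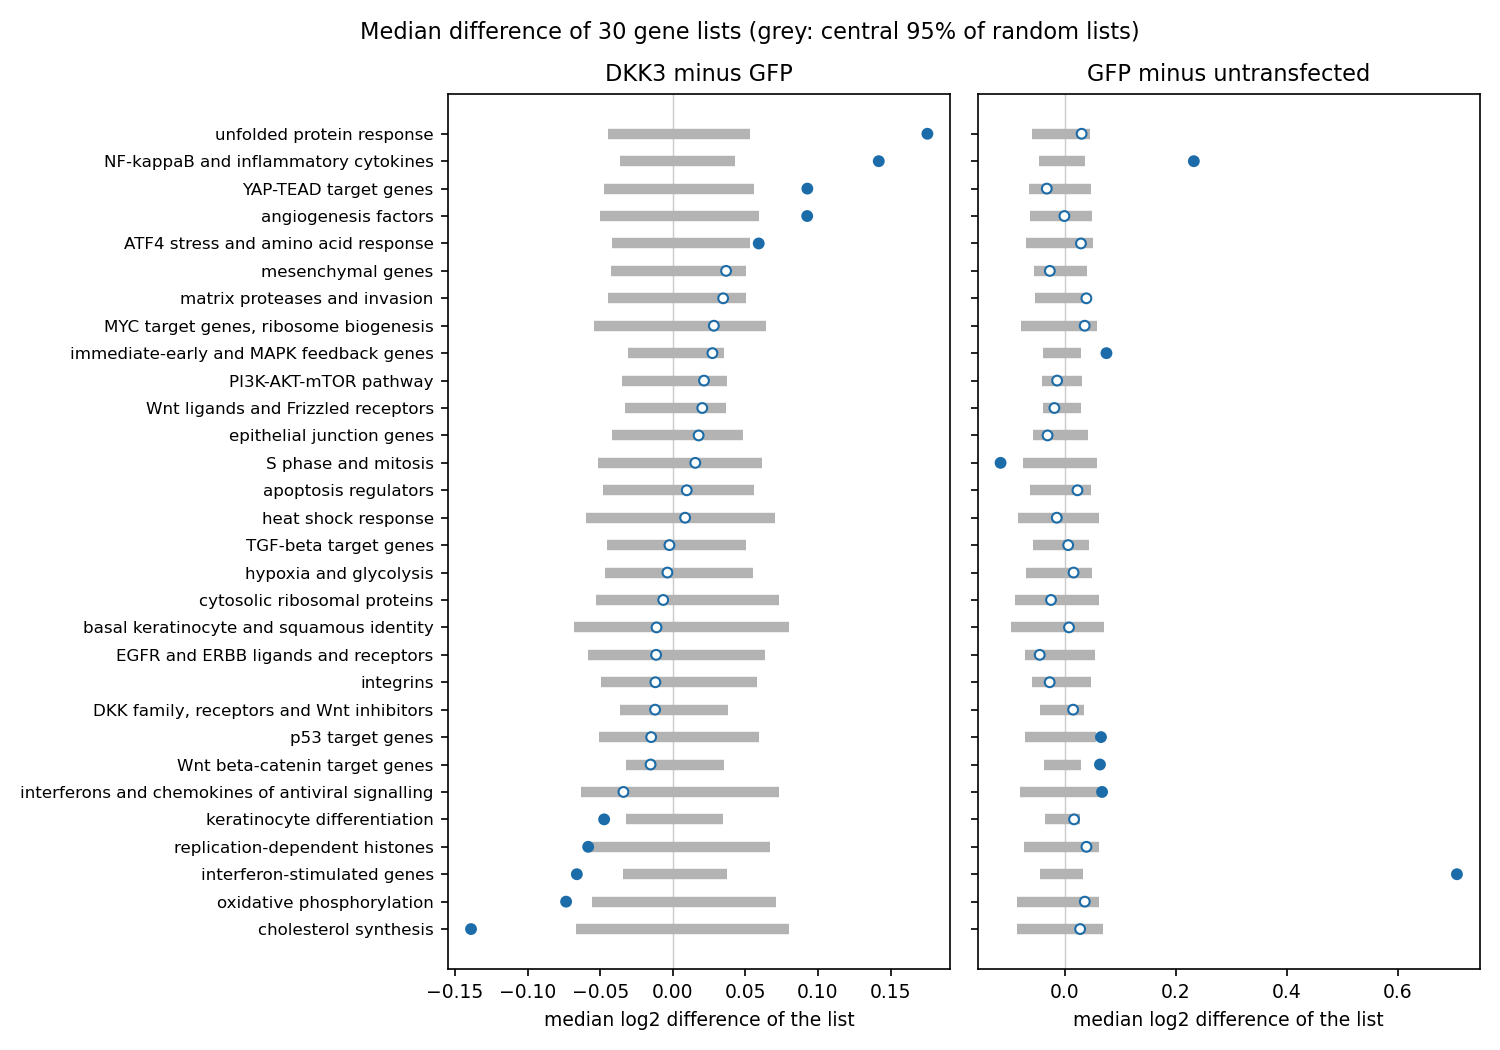
Median log2 difference of the detected members of 30 gene lists (horizontal axis, 1 point per list) for DKK3 minus GFP on the left and GFP minus untransfected on the right, on axes of different range. Grey bars span the central 95% of 10000 matched random lists and filled points lie outside them; the unfolded protein response (0.18) tops the left panel, cholesterol synthesis (-0.14) ends it, and interferon-stimulated genes (0.71) lie furthest out on the right.

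Single probes differed by far more than the list medians did. Between DKK3 and GFP, 45 of 17567 probes differed by 2-fold, 21 higher and 24 lower, and between GFP and untransfected 46 of 18064 did. The number of probes 2-fold from both other arrays was 23 for the DKK3 array (19 higher, 4 lower), 21 for the GFP array (19 higher, 2 lower) and 17 for the untransfected array (2 higher, 15 lower) of 18151. By this count the DKK3 array stood apart from the others by 2 probes more than the GFP array did. Of the 24 probes lower than on the GFP array, 19 were the ones 2-fold brighter on the GFP array than on both others.

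After DKK3, the genes furthest above both other arrays were EPN3, an endocytic adaptor of the epsin family, by 5.60 against GFP, the transcriptional corepressor NAB2 by 3.90, LDLRAD4 by 3.675, NAV3 by 3.53, the nonsense-mediated decay factor SMG6 by 3.37, ABHD14B by 3.25 and the kinase DYRK4 by 2.11. Smaller differences were those of XYLT2 (1.70), OR7A10 (1.66), AGR2 (1.60), TMPRSS13 (1.499), the checkpoint protein RAD17 (1.45) and RTKN (1.17), and PAGE3 (0.92) and HCRTR1 (0.89) stayed under 2-fold. AGR2, a disulfide isomerase of the endoplasmic reticulum in secretory epithelia, was 2-fold higher on both of its probes, by 3.04-fold and 2.78-fold. LDLRAD4, XYLT2 and RTKN had other detected probes, and these differed by -0.015, by 0.040 and 0.030, and by -0.33 (RTKN, on a spot of block 24). The other genes of this group rest on 1 detected probe. The EPN3 spot lies in the same column and row as the DKK3 spot, 4 blocks earlier, and held 13.6% of its blank-corrected intensity on the DKK3 array.

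The genes furthest below both other arrays were PDCD10, an adaptor of the cerebral cavernous malformation complex, at -1.93 against GFP, BRI3BP at -1.50, the glycogen branching enzyme GBE1 at -1.21 and the phosphate transporter SLC20A1 at -1.04. Under 2-fold were CCNA2, cyclin A2 of S phase and mitosis (-0.89), IL1B (-0.79), PSMB4 (-0.78), SEMA3C (-0.74), PFDN6 (-0.73), KCNMA1 (-0.72), ME1 (-0.72), PTPN12 (-0.71), GPI (-0.70), EMC6 (-0.70) and CLASRP (-0.67). All but BRI3BP and CLASRP were printed in blocks 22 to 24, and 9 of the 15 in the first row of blocks 22 and 23. The other probes of SLC20A1, PFDN6 and CLASRP, printed elsewhere, differed by -0.29, 0.027 and -0.059. 4 probes were 2-fold below both others, 3 with block and row medians subtracted and 1 without blocks 22 to 24.

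**Figure D2:**
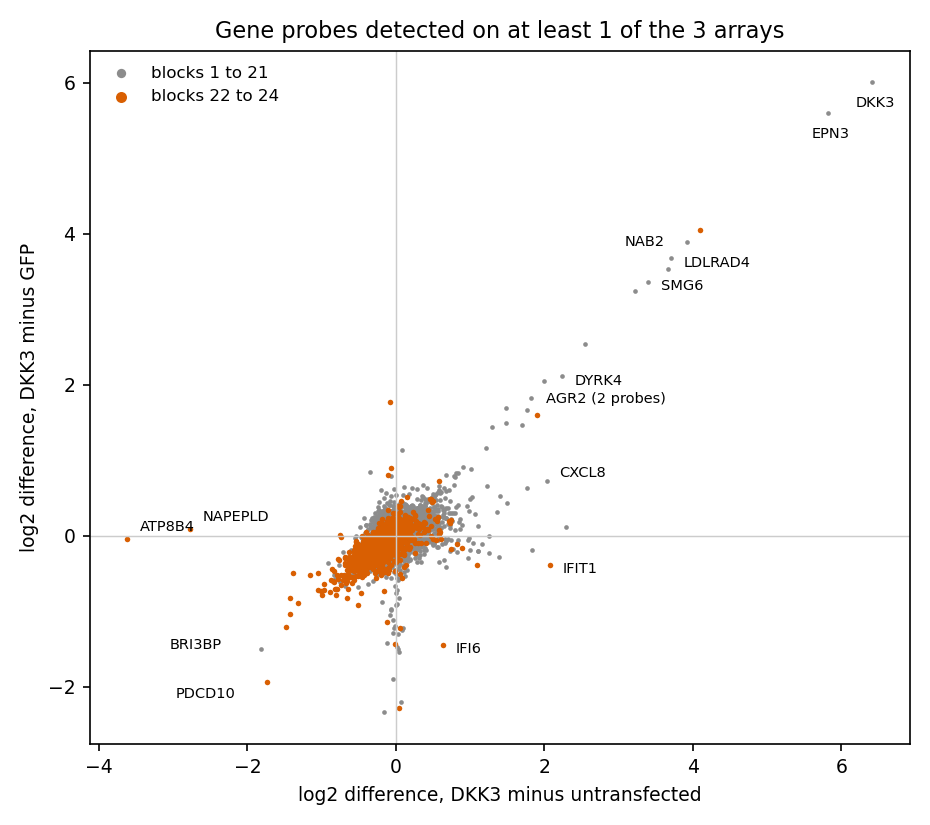
Each point is 1 of the 18151 gene probes detected on at least 1 array, with its log2 difference DKK3 minus untransfected (horizontal) and DKK3 minus GFP (vertical); probes of blocks 22 to 24 are coloured. DKK3 (6.42 and 6.01) and EPN3 (5.82 and 5.60) lie at the upper right, probes bright on the GFP array alone fall straight down from the centre, and the coloured probes reach furthest to the lower left, with PDCD10 at -1.74 and -1.93.

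Transfection with the GFP plasmid was accompanied by a broad interferon response. Of 43 detected interferon-stimulated genes 42 were higher on the GFP array than on the untransfected array, 15 of them by 2-fold, with a median difference of 0.71 or 1.63-fold (percentile 100). On the DKK3 array 42 of 43 were higher than in untransfected cells, 10 of them by 2-fold, with a median of 0.58. The RNA-binding antiviral proteins IFIT1, IFIT3 and IFIT2 were higher by 2.47, 2.01 and 1.25 with GFP, and by 2.08, 1.83 and 1.25 with DKK3 (the other IFIT2 probe by 1.06 and 0.89). IFI27 (1.68), MX1 (1.49) and IFI44 (1.27) were higher with GFP too. MX2 was higher by 1.88-fold with GFP and 1.76-fold with DKK3 on 1 probe, and by at least 2.36-fold and 2.05-fold on the other, not detected in untransfected cells.

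Inflammatory genes were higher after transfection as well. The NF-κB list had a median of 0.23 with GFP (27 of 32 above 0, 4 at 2-fold) and 0.36 with DKK3 (28 of 32, 6 at 2-fold). CXCL8 was higher by 1.31 with GFP and 2.03 with DKK3, CXCL2 by 1.14 and 1.77, CSF2 by 1.06 and 1.49, and IL6 by 1.04 and 1.36. Immediate-early genes (median 0.075, 31 of 34 above 0), p53 targets (0.065; GADD45A 0.78, BBC3 0.55, CDKN1A 0.44), Wnt and β-catenin targets (0.064; PLAUR 0.54, CD44 0.38) and antiviral interferons and chemokines (0.067; CXCL10, not detected in untransfected cells, at least 1.22-fold higher) also stood above random lists with GFP. In the authors' deposited values, where the median of all probes was shifted by -0.199, the immediate-early, p53 and Wnt medians turned to -0.0385, -0.0884 and -0.0275. The antiviral list kept its place in only 6 of 12 alternatives, and the p53 and Wnt lists lost theirs in 1 more each, without blocks 22 to 24 and with block and row medians subtracted. S phase and mitosis genes stood below them, at -0.12 with 9 of 37 above 0 (KIF20A -0.53, KIF11 -0.455). 7 of 30 lists stood apart in this comparison, and neural markers again did, at 0.081 with GFAP at 1.20.

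Of the 46 probes that differed by 2-fold between GFP and untransfected cells, 41 were higher and 5 lower. This balance turned in the authors' deposited values, shifted by -0.199 over all probes, with 99 higher and 170 lower. COQ5, of ubiquinone synthesis, was higher by 2.18 with GFP and 2.30 with DKK3 on 1 probe, and by 0.14 and 0.11 on the other. The lowest values were ATP8B4 at -3.58 and NAPEPLD at -2.87, whose spots are neighbours in block 23 and were bright on the untransfected array alone. The other 3 of the 5, SIAE at -1.06, named after its value was seen, and probes without a gene name, were not 2-fold lower with DKK3. Ranked by the smaller of their differences with GFP and with DKK3, the genes after ATP8B4 and NAPEPLD were the nuclear lamina gene LMNB1 (-0.89 with GFP), DNAJC21 (-0.74), the condensin subunit NCAPH (-0.63), MN1 (-0.56), WFDC3 (-0.53), ZRANB2 (-0.50), RUVBL1 (-0.60) and NPEPPS (-0.48). 6 of these 10 lie in blocks 22 to 24.

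Between DKK3 and untransfected cells, which differ in transfection and in DKK3, 53 of 18110 probes differed by 2-fold, 40 higher and 13 lower. Without blocks 22 to 24 they were 36 and 1, and with block and row medians subtracted 39 and 11. In the authors' deposited values the balance turned, with 101 higher and 356 lower. 11 of 30 lists stood apart. YAP-TEAD targets (0.031), oxidative phosphorylation (-0.027), histones (-0.030) and keratinocyte differentiation (-0.022), apart between DKK3 and GFP, lay inside the random range here. The unfolded protein response, NF-κB and interferon-stimulated lists, given above, stood apart here too. Besides the lists already given, the ATF4 list (0.087; DDIT3 0.96, WARS1 0.80), antiviral interferons and chemokines (0.11), immediate-early genes (0.0815; HBEGF 1.22), matrix proteases (0.066; SERPINB2 0.82, PLAU 0.52) and angiogenesis factors (0.10; EFNA1 0.80, VEGFC 0.57) stood above random lists. With the authors' deposited values, shifted by -0.235 over all probes, the ATF4 and protease medians turned to -0.1182 and -0.0671, and those of the other 3 of these lists were 0, the antiviral list no longer standing apart. Cholesterol synthesis (-0.094; INSIG1 -0.53, IDI1 -0.49), S phase and mitosis (-0.074) and TGF-β targets (-0.0545) stood below, the last of them in only 5 of 12 alternatives, and above 0 when blocks 22 to 24 were left out (0.0215).

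The comparisons of DKK3 with GFP and with untransfected cells share the DKK3 array. Their differences correlated at 0.62 across probes, against 0.50 in simulated arrays with no effect, and their covariance was 0.0203 against 0.0034 simulated. The simulated noise was normal, at the robust SD of GFP minus untransfected, while correlation and covariance also take in the few probes that differ widely. The spread that the DKK3 array added on its own was 0.1425 as an SD and 0.0542 as a robust SD. The excess thus does not separate an effect from such probes. The share of probes with the same sign was 64.7%, below the 66.6% simulated. 19 probes were 2-fold higher in both and 4 lower in both, where independent lists would share 0.046 and 0.017 and simulated arrays 0 and 0. Neither value allows for spots bright on a single array, and the GFP array had as many probes above both others (19). The comparisons of GFP and of DKK3 with untransfected cells share the untransfected array. Their correlation was 0.54 and their covariance 0.0165, against the same simulated values, and the same sign was found in 68.9% of probes. 15 probes were higher and 2 lower in both, where independent lists would share 0.09 and 0.004 and simulated arrays 0 and 0. In both pairs the simulated arrays shared an array in the same way, but their noise held no widely differing probes. The covariance of a pair is the variance that the shared array adds on its own. As an SD that was 0.1425 for DKK3 and 0.1284 for untransfected, and as a robust SD 0.0542 and 0.0574. The simulated noise was set on the robust scale. The excess in covariance and in shared 2-fold probes thus follows from the widely differing probes, whatever their cause, and no conclusion is drawn from it.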

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

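The test of uneven brightness on the unfolded protein response and the test of carry-over over the whole array were set before their results were seen, and the other tests of this part were chosen after the patterns had been seen. The second brightness column of the scanner files also held the DKK3 signal, with 66.3 times the intensity on the DKK3 array as on the GFP array. This column followed the spot column closely, so it is no independent measurement. In the spot column the ratio was 85.8. Of the 19 probes at least 2-fold higher on the DKK3 array than on both others, 17 were so in the second column as well. These are raw intensities. Of the 15 genes named as lower, 12 were below both other arrays in the raw second column, and IL1B, GPI and CCNA2 were not below GFP. Once it was scaled to equal medians 13 were below both, and IL1B and GPI were still not below GFP. CCNA2 read 479 on the DKK3 array and 459 on the GFP array in the raw second column, against 499 and 1093 in the spot column. These counts do not take in the size of a difference.

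The genes of the unfolded protein response were higher on the DKK3 array than on the GFP array by a median of 0.175. Uneven brightness of the arrays as the cause is argued against by the median of 0.224 with block and row medians subtracted and 0.191 without blocks 22 to 24. A stronger response to transfection as a whole is argued against by the interferon-stimulated genes, which were lower on the DKK3 array (median -0.066), although the NF-κB list, also higher after transfection, was higher still on it (0.14). A load of the endoplasmic reticulum by the secreted DKK3 protein may account for the pattern, a hypothesis that goes with values of 0.175 against GFP and 0.214 against untransfected cells. With 1 culture per plasmid it cannot be told apart from a difference between the cultures or RNA samples.

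Single probes far higher on the DKK3 array could reflect something other than the level of their gene. The 4 other detected probes of LDLRAD4, XYLT2 and RTKN had a median difference of 0.008 (the RTKN probe, at -0.33, lies in block 24), as a signal of 1 probe alone would give, while the probe of AGR2 other than its highest was higher by 1.475, which argues against it for AGR2. For EPN3, carry-over of the kind a whole array would show is argued against by other bright spots. Of 333 readings over 10000, 76% had a spot 4 blocks earlier with less than the EPN3 share. The readings come from all 3 arrays, so the same spot can count on more than 1 array and they are not 333 separate spots. A mix-up or spill between the EPN3 and DKK3 spots alone stays open, as EPN3 held at least 22.6% of the DKK3 signal on the other arrays against 13.6% on the DKK3 array, but an own signal of EPN3 would give that too. Beyond the other probes, a real difference in these transcripts was not tested. EPN3 and the other genes that rest on 1 detected probe had no such probe.

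Of the 15 genes named as lower on the DKK3 array, 13 lie in blocks 22 to 24, which hold 12.7% of the eligible probes. Random placement would give as many with a probability of 1.8e-10 for blocks fixed beforehand. The blocks were chosen after the pattern had been seen, and the probability does not allow for that choice. The medians of all probes of blocks 22, 23 and 24 were -0.0575, -0.0286 and -0.0658, and probes over 8 on the log2 scale had a median of -0.152 in these blocks against 0.019 in the others. Blocks dimmer throughout by the same factor are argued against as the whole cause, since 10 of the 15 lowest genes still lay there with the median of spots of like brightness in each block subtracted. A dim patch within these blocks may account for part of the pattern, as the 9 other probes, printed outside the blocks, of genes lower by at least 0.4 inside them had a median difference of -0.045, which faults of single spots would give too. For the genes without another probe, PDCD10 and CCNA2 among them, no value separates a patch from the gene's level.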

How the results depend on the processing

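No paired analysis was possible because each group is 1 array. Leaving out blocks 22 to 24 and subtracting block and row medians were chosen after seeing the data. Under the alternatives 74 values of the main results stayed close to the reported ones and 18 moved. A count stayed close when it lay within 1.5-fold of the reported one. The DKK3 difference did so when it lay within 0.084, the robust SD of GFP minus untransfected. DKK3 minus GFP stayed above 6, at 6.50 with median scaling, 6.52 with 75th percentile scaling, 6.63 with cyclic loess, 6.12 with plain subtraction and 6.685 in the deposited values; quantile normalization lowers the brightest probe by construction. Counts of 2-fold probes were given for DKK3 against GFP, GFP against untransfected, DKK3 against untransfected, and DKK3 against both others. They were 45, 46, 53 and 23 in the reported setting, 140, 147, 179 and 71 with plain subtraction, 219, 269, 457 and 111 in the deposited values, and 116, 120, 199 and 63 at 1.5-fold. With an offset of 16 the counts were 66, 67, 91 and 34, of which only the 91 was counted as moved. A smaller or no offset may spread the dim probes, so signal over background may limit these counts, but no count was split by brightness. The deposited values also differ in scaling. With no background correction the counts were 55, 60, 70 and 26.

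In the deposited values the median of all probes moved by -0.199 for GFP and -0.235 for DKK3 against untransfected, and 36.8% and 22.1% of the 2-fold probes were higher (99 of 269 and 101 of 457), against 89.1% and 75.5% in the reported setting. Relative to that shift the list medians still lay high among random lists, but their signs turned for Wnt and β-catenin targets (-0.0275), p53 targets (-0.0884) and immediate-early genes (-0.0385) with GFP, and for matrix proteases (-0.0671) and the ATF4 list (-0.1182) with DKK3. TGF-β targets with DKK3 turned to 0.0215 without blocks 22 to 24; the cause was not tested. Of the list medians, 647 kept their place under the alternatives, 33 no longer stood apart, 10 newly did and 6 that had stood apart turned sign. Turns of sign were not counted for lists inside the random range. Ranges for DKK3 minus GFP were 0.15 to 0.26 for the unfolded protein response, 0.105 to 0.32 for NF-κB, -0.19 to -0.11 for cholesterol synthesis and -0.13 to -0.052 for interferon-stimulated genes.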

Other observations

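The 2 arms of the transfection response differed in direction between the DKK3 and GFP arrays. Interferon-stimulated genes were a little lower with DKK3 than with GFP, with IFI35 at -0.32, IFI27 at -0.29, MX1 at -0.23 and IFIT3 at -0.18. Genes of the NF-κB list were higher with DKK3, with CSF2 at 0.43 and IL6 at 0.32. The chaperones HSP90B1 and CRELD2 of the endoplasmic reticulum were higher with DKK3 than with GFP by 0.36 and 0.27, and XBP1 by 0.17. Against untransfected cells these genes were higher by 0.56, 0.63 and 0.58 with DKK3 and by 0.21, 0.36 and 0.41 with GFP. Whether the difference between the plasmids exceeds that between 2 cultures was not tested, since each had 1 array.

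The GFP array had its own bright probes, as many as the DKK3 array (19 each, 15 of them with a gene name). They included TDRP, RTL10, PHKG1, GRIP2 and IFI6, higher than on both other arrays by at least 2.20, 2.18, 1.85, 1.54 and 1.45, and were singled out after their values were seen. ATXN7L2, at 1.02, had another detected probe, which differed by 0.0005 from untransfected cells. The highest probe without a gene name on the DKK3 array stood 4.05 above both others.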
